A study of Mus musculus with 2 samples.

How the data were processed

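The series holds single-cell RNA sequencing of mouse medullary thymic epithelial cells (mTECs) sorted as EPCAM-positive and Ly51-negative, prepared with the 10x Genomics 3' kit and sequenced on an Illumina NovaSeq. There are 2 libraries, 1 per genotype, labelled Foxn1-Cre(+) Ikaros+/fl and Foxn1-Cre(+) Ikarosfl/fl. Each was assigned to its group by the genotype field of its labels. The submitters' names for the matrices give the genotypes the other way round, as knockout for the library labelled +/fl and as control for the library labelled fl/fl. This conflict could not be settled from the values, so every direction is given between libraries as labelled. Labels state neither the exons removed by the floxed allele nor the age, sex or number of the mice.

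The deposited values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger, per the submitters' processing notes, which also name Seurat without a role and give no version of either. The matrix headers carry the software version string 3.1.0. Genome build and annotation are not given in the sources used here. Both matrices list the same 31053 genes by Ensembl identifier and symbol. No deposited barcode has under 500 UMIs. No normalised matrix, cell annotation or doublet call of the authors was used here. Sequencing reads were not analysed here. Positions in the report were looked up by Ensembl identifier in the GENCODE M21 annotation of GRCm38, and no value depends on them.

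Cells with at least 500 detected genes, at least 1000 UMIs and at most 15% mitochondrial UMIs passed, which were 69.8% of 7304 barcodes in the library labelled +/fl and 74.0% of 11095 in the library labelled fl/fl. Scrublet, run per library through scanpy 1.11.5, marked 0.0196% and 0% of those cells by its automatic threshold, under the lower bound of 0.5% set for a working call. The cells with the highest doublet scores were therefore removed at 0.8% per 1000 cells, 208 cells (4.08%) and 539 cells (6.57%). This left 4891 and 7669 cells with medians of 10731 and 8187 UMIs, 3268 and 2747 genes, and 6.28% and 4.87% mitochondrial UMIs.

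Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 21 clusters. Clusters were named from 21 fixed marker lists. A cluster took the name of the list with the highest mean log2 fold of its members over the median of the other clusters, if at least 3 members were detected in at least 10% of its cells and at 2-fold or more over that median. It also had to hold no more markers of another class than of its own among its 10 leading genes. Names mean resemblance to the marker list only. The marker lists for enterocyte-hepatocyte, muscle, ionocyte, pancreatic, parathyroid, cortical epithelial, B-lineage and erythroid cells named 0 clusters. Clusters carrying non-epithelial markers at an epithelial Epcam level stayed unnamed. That rule was set after the clusters were seen and keeps 1 cluster out of the classes, with 4.74% of cells in the library labelled +/fl and 0.352% in the library labelled fl/fl. The scoring rule itself was also changed after the clusters were seen, from a count of markers to the mean over the whole list. A clustering without 6 sex-linked genes was tried after the sex difference was seen and dropped, since 0 of the 6 were among the variable genes.

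With 1 library per genotype no test was made, and no p-value, standard error or count of changed genes is given. UMIs were summed over the cells of a library or class and divided by the total (CPM, UMIs per 1000000) with exact Poisson intervals at 95%. Ratios are log2 of the library labelled fl/fl over the library labelled +/fl, with 1 CPM added to both. Shares of cells carry exact Clopper-Pearson intervals. All intervals cover counting error only. A fold against a library with 0 UMIs is a bound computed at a floor of 3 UMIs over the cells summed. Shares of cells with a UMI of a gene were compared after each cell was thinned to 2000 UMIs, which left out 324 cells of the library labelled +/fl and 797 of the library labelled fl/fl. Classes with at least 100 cells in both libraries were compared gene by gene, which were Aire-stage mTEC, Immature mTEC, Cycling, Tuft, and Myeloid and dendritic.

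Named genes follow a fixed rule. They are the 10 highest and 10 lowest ratios over all kept cells, and the 6 highest and 6 lowest in each class, among genes with at least 50 CPM in either library and at least 50 UMIs over both. Members of 15 gene lists and of the marker lists may also be named. Single values of some list members are not reported here. The gene lists cover the Ikaros family, transcription regulators of mTECs, reported Aire-induced antigens, the MHC class II and class I pathways, costimulation, NF-kB and TNF receptors, interferon-stimulated genes, chemokines, cell cycle, keratins, tuft taste and effector genes, dissociation stress, apoptosis and p53, and sex-linked genes. Of the 318 listed genes, 1 (Spt1) was not in the matrices. A member counts as measured at 5 CPM or more in either library. The median ratio of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these libraries. Genes with near-identical copies are uncertain where tags could be shared between copies. Among named genes these are the Klk1b kallikreins, Sprr2a3, Dcpp1, Chil4, Gm8113, Saa1, Saa3, Hamp2, Trbc2 and Hspa1a. Tsix overlaps Xist on the other strand, and a stranded count is not stated.

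The ratio step was tested on simulated counts for 11632 genes drawn at the real depths. Of the genes changed by 1.5, 2, 4, 0.5 and 0.25 times, 100% came back within 0.2 on the log2 scale, as did 99.8% of the 11432 unchanged genes. The intervals held the true value for 92.5% to 97.5% of changed genes, by fold size, and for 95.1% of unchanged genes. The counts were Poisson draws at whole-library depths, as the intervals assume, so this coverage was set in advance. Neither class sums nor variation between cells or libraries was simulated. Groups, marker and gene lists, the named-gene rule, filters and alternatives were fixed before the data were examined. Alternatives covered clustering resolution, seed, variable genes, marker genes left out, doublets kept, a stricter cell filter of 1000 genes, 2000 UMIs and 10% mitochondrial UMIs or no filter, thinning, libraries clustered apart, an epithelial denominator, TMM factors, per-cell CPM, another total, other pseudocounts and another CPM minimum. Tools were Python 3.11.15 with anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and edgeR 4.0.16 under R 4.3.3 for TMM factors only.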

Results

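The series sets mTECs of mice with a conditional deletion of Ikaros, the transcription factor encoded by Ikzf1, beside those of control mice. There were 2 single-cell libraries, 1 labelled Foxn1-Cre(+) Ikaros+/fl (labelled +/fl) and 1 labelled Foxn1-Cre(+) Ikarosfl/fl (labelled fl/fl). The submitters' names for the matrices give these genotypes the other way round, so each direction holds between libraries as labelled. The library labelled +/fl held 7304 barcodes and 85260592 UMIs, of which 4891 cells with 66675011 UMIs were kept. The library labelled fl/fl held 11095 barcodes and 99871505 UMIs, of which 7669 cells with 80897462 UMIs were kept. Kept cells had medians of 10731 and 8187 UMIs. With 1 library per genotype no difference has a replicate check, and all 95% intervals cover counting error only. Sex was not shared either. Xist, the RNA of the inactive X chromosome, had 1317 UMIs per 1000000 (CPM) in the library labelled +/fl and 0.902 CPM in the library labelled fl/fl. The Y-linked Ddx3y had 0 UMIs in the first and 64.5 CPM in the second, so genotype as labelled and sex cannot be told apart.

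The first comparison asked how much Ikzf1 each library carried. Ikzf1 (ENSMUSG00000018654, chromosome 11, 11685003 to 11772926 of GRCm38) was lower in the library labelled fl/fl, with 37.7 CPM (36.4 to 39.1) against 64.5 CPM (62.6 to 66.4) in the library labelled +/fl. Tuft-like cells held 55.3 CPM (52.1 to 58.5) and 18.0 CPM (15.01 to 21.5) of it, a 3.06-fold difference. Aire-stage cells held 109 CPM (105 to 114) and 49.3 CPM (47.2 to 51.5), a 2.21-fold difference. The libraries differed in the clusters behind these classes, and Ikzf1 was not compared within clusters. Aire-stage cluster 3 held 842 cells labelled +/fl and 95 labelled fl/fl, and Tuft cluster 5 held 1287 and 297. Cycling cells held 67.9 and 65.7 CPM, T-lineage cells 185 and 170 CPM, and Immature mTECs 15.8 and 12.8 CPM, and the counting intervals of these ratios included 1. The T-lineage log2 ratio ran from -0.75 to -0.1 over the alternatives, so T-lineage cells were not firmly level. Myeloid and dendritic cells held 61.3 (54.1 to 69.1) and 44.4 CPM (36.4 to 53.7), a 1.38-fold (1.10 to 1.74) difference. Lower counts were therefore not confined to epithelial classes, but whether free RNA from other cells carried them there was not tested. After thinning to 2000 UMIs, Ikzf1 was found in 10.4% (9.55 to 11.3) of 4567 cells labelled +/fl and 6.42% (5.85 to 7.02) of 6872 labelled fl/fl, and without thinning in 37.5% and 23.2%. In Immature mTECs, the compared class with the lowest level, the thinned shares were 3.40% and 2.52%, at median depths of 9774 and 6045 UMIs. All 4 measured genes of the Ikaros family, Ikzf1 among them, were lower in the library labelled fl/fl over all kept cells, with a median log2 ratio of -0.51. Class shares enter that value, and within classes the family did not move as one. Its genes were higher in 2 of 4 in Immature mTECs (0.05) and Cycling cells (0.04). In Myeloid and dendritic cells 4 of 5 were higher (0.24), against 0 of 4 in Aire-stage (-0.45) and 1 of 4 in Tuft (-0.31). The labels do not give the deleted exons, and 3' tags gather near the 3' UTR in the last of 8 exons (11769582 to 11772926), so this level does not settle which library carries the deletion.

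**Figure D1:**
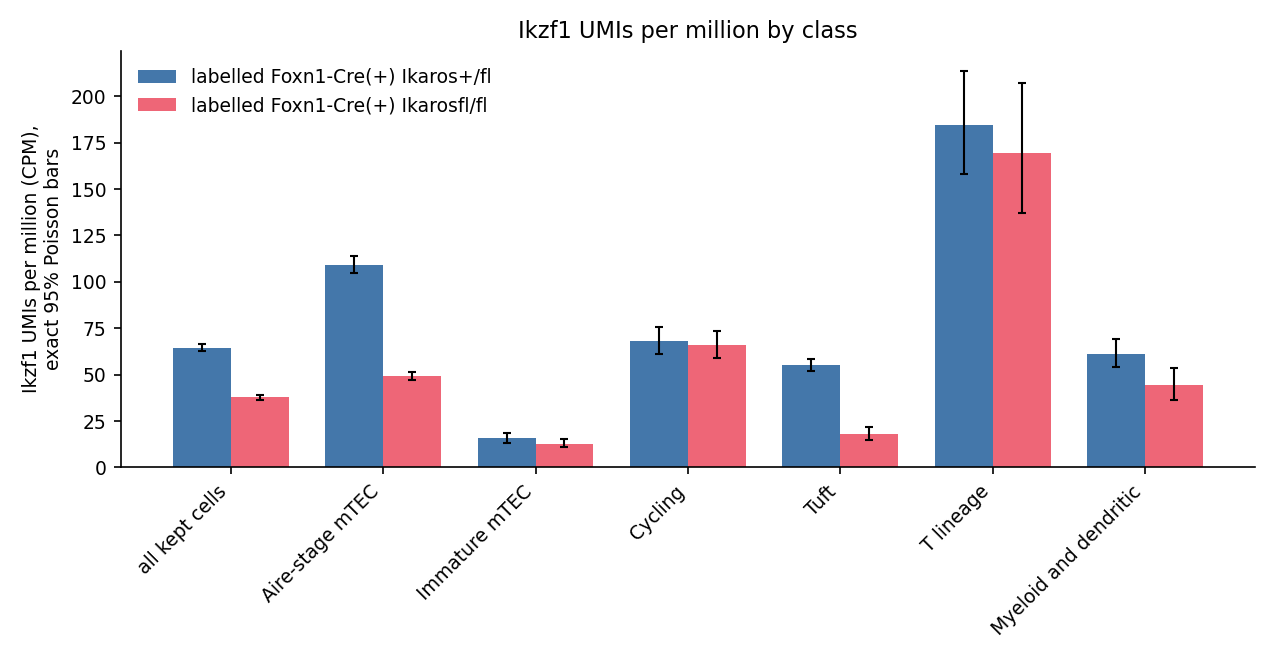
Ikzf1 level (CPM, UMIs scaled to the library's or class's total) for each class and library, with exact Poisson 95% intervals over summed UMIs. The library labelled fl/fl is lower in Tuft (18.0 against 55.3 CPM) and Aire-stage mTEC (49.3 against 109 CPM), and close to the other in Cycling (65.7 against 67.9 CPM).

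Cell classes were then compared between the libraries. Tuft-like cells, chemosensory epithelium that carries Trpm5 and Pou2f3, made up 39.1% (37.7 to 40.5) of the library labelled +/fl and 10.9% (10.2 to 11.6) of the library labelled fl/fl, a 3.58-fold difference. Aire-stage cells, a class named on Aire and other markers, made up 19.7% (18.6 to 20.9) and 42.1% (40.9 to 43.2). The other named mimetic classes also held larger shares of the library labelled fl/fl. Shares of a library have a common total, so the smaller Tuft share alone raises all its other shares. Class shares among the cells outside Tuft were not compared. Near-equal shares, as of Immature mTECs below, therefore need not be near-equal among those cells. Microfold-like cells with Gp2 and Ccl20 were 1.12% (0.848 to 1.46) and 5.20% (4.72 to 5.72), and neuroendocrine-like cells with Chga were 0.634% and 3.52%. Keratinocyte-like cells with Krt10 were 1.21% and 3.74%, secretory-like cells 1.14% and 3.99%, and ciliated-like cells with Foxj1 0.327% and 0.939%. These 5 classes together were 4.44% (3.88 to 5.05) and 17.4% (16.6 to 18.3). With the libraries clustered apart, cells named Microfold were 13.7% and 2.59%, but 597 of these 670 cells labelled +/fl were Aire-stage in the joint clustering and 55 Microfold. Cells named Neuroendocrine were 3.27% and 3.34%, and 30 of these 160 cells labelled +/fl were Neuroendocrine in the joint clustering. The microfold-like cluster was led by enterocyte genes too, among them Fabp1 and Apoa4. Immature mTECs were 19.0% (17.9 to 20.1) and 20.1% (19.2 to 21.01), and Cycling cells 3.21% and 3.09%. Myeloid and dendritic cells, which the EPCAM sort would remove, were 7.32% (6.61 to 8.09) and 4.24% (3.80 to 4.71), and T-lineage cells 1.74% and 1.54%. Endothelial-like cells were 0.368% and 0.156%, and fibroblast-like cells 0.388% and 0.156%. An unnamed cluster with Epcam and the matrix genes Col3a1 and Dcn held 4.74% and 0.352%. With the marker genes left out of the clustering, Tuft was 38.7% and 10.9% and Aire-stage 16.8% and 43.3%. The Aire-stage share reversed at resolution 2, to 18.3% and 15.4%, where 12.5% and 32.3% of cells stayed unnamed.

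**Figure D2:**
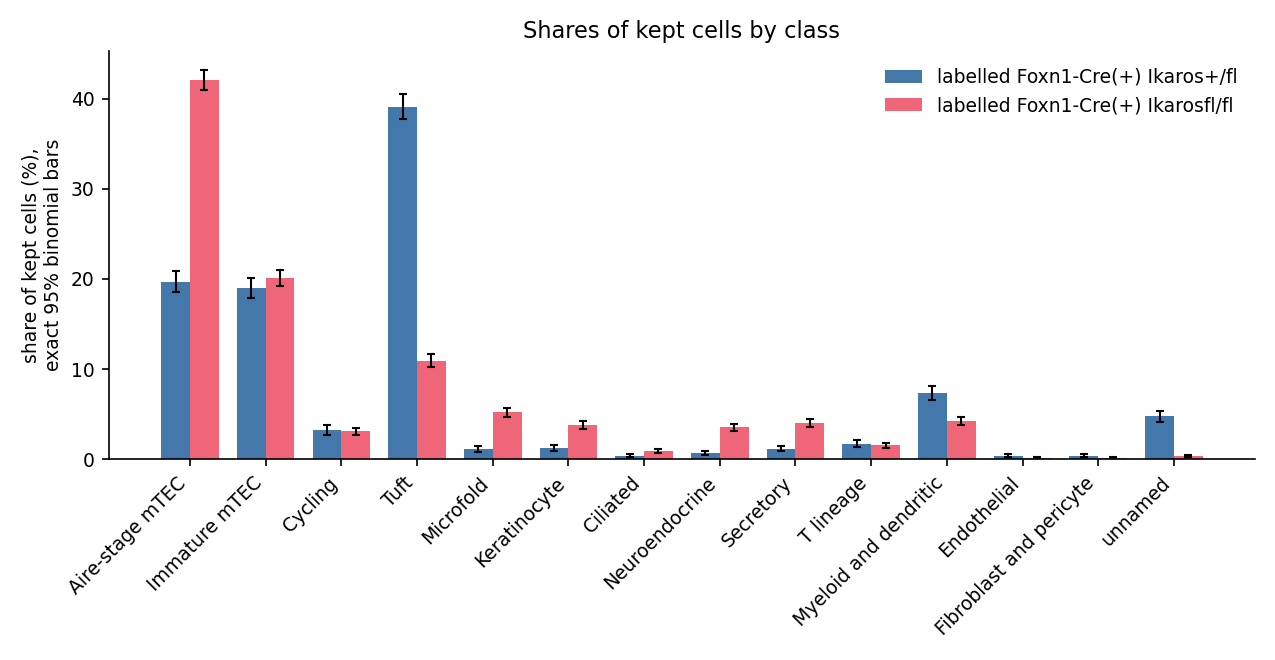
Share of kept cells (percent) in each class, per library as labelled, with exact binomial 95% intervals. Tuft is higher in the library labelled +/fl (39.1% against 10.9%), and Aire-stage mTEC is higher in the library labelled fl/fl (42.1% against 19.7%).

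Shares of cells with single marker genes needed no classes. Aire (ENSMUSG00000000731, chromosome 10, 78030022 to 78043610) had a UMI in 15.8% (14.7 to 16.9) of cells labelled +/fl and 30.6% (29.5 to 31.7) of cells labelled fl/fl after thinning, against 42.4% and 56.3% without it. Its shares in Myeloid and dendritic cells were 16.0% and 17.3%, at median depths of 9666.5 and 6184 UMIs before thinning, in T-lineage cells 6.58% and 21.2%, and in Immature mTECs 8.49% and 11.3%. These differed too much to give 1 background for Aire, so its shares are not read as shares of expressing cells. Within the Aire-stage class Aire was found in 42.6% (39.2 to 46.0) and 51.7% (49.8 to 53.5) of thinned cells. Trpm5 (ENSMUSG00000009246, chromosome 7, 143069153 to 143094642), the cation channel of taste and tuft cells, was found in 31.6% (30.3 to 33.0) and 9.27% (8.59 to 9.98), against 5.44% and 3.70% in Myeloid and dendritic cells. Fezf2 (ENSMUSG00000021743, chromosome 14, 12342094 to 12348189) was found in 20.6% and 33.1%, against 10.5% and 7.82% in Myeloid and dendritic cells. The milk protein gene Csn2 was found in 18.7% and 38.5%, against 14.97% and 15.2% there and 4.64% and 10.99% in Immature mTECs. Gp2 was found in 1.62% and 5.46%, Chga in 2.30% and 5.76% and Foxj1 in 2.30% and 5.34%. Krt10, the marker given for keratinocyte-like cells, did not bear out their larger share. Its log2 ratio of thinned shares was 0.30, and ran from -0.42 to 0.04 at other depths and without thinning. In Myeloid and dendritic cells the shares were 0% and 1.65% for Gp2, 1.02% and 1.23% for Chga, and 1.02% and 1.65% for Foxj1. Mki67 was found in 3.37% and 3.65% and Ccl21a in 51.0% and 50.5%.

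Over all kept cells, the genes with the largest ratios were often leading genes of clusters. Muscle markers were lower in the library labelled fl/fl in 6 of 9, with a median log2 ratio of -0.63. Of these markers, 5 met the marker rule in Tuft cluster 4, and Myog is among its 10 leading genes. Saa1, an acute-phase gene of liver and gut, had 29.2 CPM labelled +/fl and 300.5 CPM labelled fl/fl, Fabp9 had 7.26 and 204 CPM, and the trefoil gene Tff1 had 4.92 and 70.3 CPM. The polymeric immunoglobulin receptor gene Pigr had 6.24 and 80.9 CPM. The other autosomal genes with the highest ratios were Klk1b26, Klk1b16, Klk1b9 and Psors1c2. On the lower side Rgs13 had 688 and 113 CPM, Ptgs1, the cyclooxygenase-1 gene, 216 and 38.1 CPM, and Stmn2 194 and 30.5 CPM, followed by Adgrg6, Gpx6, Nrgn, Meg3 and Pik3cg. Of these, Klk1b26, Klk1b16, Klk1b9, Fabp9, Psors1c2, Gpx6, Adgrg6, Nrgn, Ptgs1 and Pik3cg are among the 10 leading genes of a cluster, so their ratios restate cluster sizes in part. Y-linked Eif2s3y was at least 1178-fold higher, against 0 UMIs labelled +/fl, and Ddx3y, Uty and Kdm5d also had 0 UMIs there. Xist and its antisense Tsix, with 56.5 and 1.61 CPM, were the lowest ratios.

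Among the gene lists, 14 of 15 measured tuft taste and effector genes were lower in the library labelled fl/fl over all kept cells, with a median log2 ratio of -1.44, below all 10000 random lists. The list shares Trpm5, Gnb3, Gnat3, Plcb2, Il25, Chat and Alox5ap with the Tuft markers. Its median thus restates the Tuft shares of 39.1% and 10.9% in part, which random lists do not allow for. Class shares also enter the other medians over all kept cells. Trpm5 had 215 (212 to 219) and 60.0 CPM (58.3 to 61.7), and Alox5ap 407 and 93.5 CPM. All 13 measured Aire-induced antigens were higher, with a median of 1.81, among them Csn2 (384 and 812 CPM) and insulin 2, Ins2 (3.12 and 31.7 CPM). Aire itself had 149 (146 to 151) and 327 CPM (323 to 331). All 9 MHC class II genes (median 0.81, H2-Aa 2193 and 4525 CPM), all 6 costimulation genes (0.99, Cd80 17.5 and 44.9 CPM) and all 10 MHC class I genes (0.41) were higher. So were 10 of 12 NF-kB genes (0.49), 10 of 11 apoptosis genes (0.38), and 9 of 13 chemokines (0.66, Ccl20 135 and 432 CPM). Keratins split, with 9 of 14 higher (0.45), Krt13 at 0.540 and 17.8 CPM, and the basal Krt5 and Krt14 lower at 677 and 386 CPM and at 613 and 422 CPM. The regulators had a median of 0.16, with Irf8 at 131 and 250 CPM and the tuft regulator Pou2f3 at 59.9 and 24.5 CPM. Of the cell cycle genes 16 of 18 were lower (-0.20), as were 9 of 13 interferon-stimulated genes (-0.16). Dissociation stress genes had a median of 0.10, which became -0.01 with TMM factors. Of the 5 sex-linked genes 4 were higher and 1 lower.

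**Figure D3:**
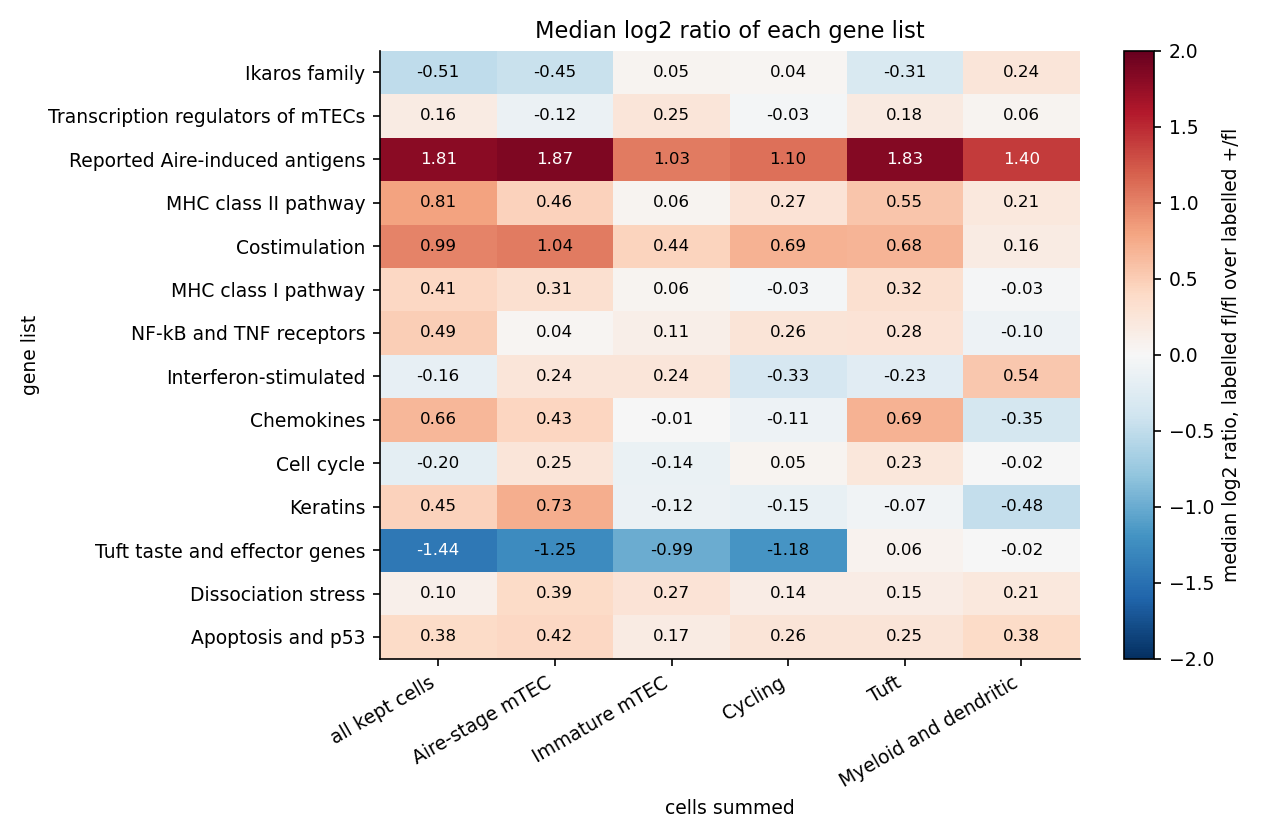
Median log2 ratio (labelled fl/fl over labelled +/fl, colour and printed value) of 14 gene lists over all kept cells and within 5 classes. Aire-induced antigens are positive in every column (1.03 to 1.87), and tuft taste and effector genes are near 0 within Tuft (0.06, or -0.01 with TMM factors) and at -1.44 over all kept cells. Only 4 antigens were measured in Immature mTEC (0.47 to 2.62 over the alternatives), and 6 each in Cycling, Tuft, and Myeloid and dendritic. In Myeloid and dendritic cells 4 of 6 were higher, and the median ran from 0.26 to 2.07.

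Within the Aire-stage class, antigens and costimulatory genes were higher in the library labelled fl/fl. All 15 measured antigens were higher, with a median log2 ratio of 1.87 (1.01 to 2.24 over the alternatives), above every random list. Ins2 had 2.09 and 56.5 CPM, somatostatin, Sst, 7.40 and 44.6 CPM, and Npy 13.1 and 53.9 CPM, but Csn2 had 1078 and 1267 CPM and Oxt 95.5 and 116 CPM. Aire, which also names the class, had 352 (343 to 360) and 528 CPM (521 to 535), while Fezf2 had 580 (569 to 591) and 534 CPM (527 to 541). Of the costimulation genes Cd86 had 1.45 and 28.5 CPM, Cd80 32.2 and 67.3 CPM and Cd274, encoding PD-L1, 41.3 and 86.3 CPM. Cd80 and Cd86, and the antigens Fabp9 and Utf1, are also markers that name the class, so they are not independent of it. Different clusters held most of this class. Cluster 3 held 842 of the 964 cells labelled +/fl and 95 of those labelled fl/fl, while clusters 7, 8 and 12 held 68, 14 and 40 cells against 977, 1423 and 730. Cluster 3 took the class name without Cd80, Cd86 or Fabp9 meeting the marker rule, while in clusters 7 and 8 all 8 markers met it. Median depth was 19976 and 10505 UMIs per cell.

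Other regulators of the Aire-stage cells parted. Irf8 had 185 and 350 CPM and Irf4 21.6 and 40.6 CPM, while Pou2f3 had 42.2 and 13.8 CPM. Pou2f3 is also a Tuft marker, and Tuft markers were lower in Immature mTECs (-1.25, 10 of 10) and Cycling cells (-1.63, 11 of 12) too. All 9 MHC class II genes were higher (median 0.46), with H2-Aa at 4224 and 6678 CPM, as were 9 of 10 MHC class I genes (0.31), 10 of 11 apoptosis genes (0.42) and all 16 stress genes (0.39). Apoptosis and stress genes were not particular to this class. Their medians were 0.25 and 0.15 in Tuft cells, and 0.38 (11 of 11 higher) and 0.21 (14 of 16) in Myeloid and dendritic cells. Among chemokines Ccl22 had 21.7 and 159 CPM and Ccl5 339 and 867 CPM, but Cxcl9 had 839 and 473 CPM, and the list median of 0.43 became -0.12 with per-cell CPM. Keratins had a median of 0.73, with Krt13 at 0.697 and 30.5 CPM and Krt14 at 567 and 275 CPM. Markers of other classes moved too, keratinocyte (1.61, 11 of 11 higher) and enterocyte-hepatocyte (1.36) with higher medians and Immature mTEC (-0.85) with a lower one. Tuft genes were lower (-1.25), and Trpm5 had 49.1 and 11.8 CPM here against 591 and 575 CPM in the Tuft class. The highest ratios outside the Y chromosome were Tff1 (1.02 and 54.6 CPM), Klk1b26, Dcpp1 and Ins2. Lowest after Xist were Fcrls (109 and 2.94 CPM), 4922502D21Rik, Rgs13, Gpx6 (462 and 39.6 CPM) and Stmn2. Gpx6 and 4922502D21Rik lead cluster 3 and Klk1b26 leads cluster 12.

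Immature mTECs were the class of Ccl21a and Krt5. Krt5 had 2544 (2512 to 2576) and 1558 CPM (1534 to 1582), Krt14 1999 and 1429 CPM, and the chemokine gene Ccl21a 16426 and 15078 CPM. All 13 interferon-stimulated genes were higher in the library labelled fl/fl, with a median of 0.24, among them Irf7 (131 and 203 CPM) and Stat2 (53.5 and 85.3 CPM). Markers of other classes differed by more, with medians of -1.25 for Tuft (10 of 10 lower), 0.78 for Aire-stage (7 of 7 higher), 1.98 for enterocyte-hepatocyte (3 of 4 higher), 0.59 for Microfold (5 of 7 higher) and -1.34 for fibroblasts (3 of 3 lower). Of the regulators 11 of 15 were higher (0.25). Stress genes were higher in 15 of 16 (0.27), with Hspa1a at 1142 and 1838 CPM. MHC class II genes had a median of 0.06. Lowest after Xist and Tsix were the keratinocyte-associated Ly6d (458 and 122 CPM) and Krtdap (622 and 168 CPM), then Sostdc1 and Stmn2. Highest after the Y-linked genes were Chil4 (0.516 and 62.1 CPM, from 5 and 638 UMIs), Gm8113, Fabp4 and Sprr2a3. The Chil4 ratio of 5.38 was 2.21 with the stricter filter. Clusters 0 and 10 held 555 and 374 cells labelled +/fl and 1073 and 468 labelled fl/fl.

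Cycling cells carried proliferation genes at close levels, with Top2a at 402 (385 to 420) and 423 CPM (405 to 442) and Mki67 at 312 (297 to 328) and 373 CPM (356 to 391). Aire had 229 and 393 CPM in them. All 9 MHC class II genes were higher in the library labelled fl/fl (median 0.27), and 9 of 13 interferon-stimulated genes were lower (-0.33, Isg15 169 and 106 CPM). Markers of other classes differed as well, with medians of 0.83 for Aire-stage (7 of 7 higher), -0.51 for Immature mTEC and -1.22 for cortical epithelium (5 of 6 lower). The highest ratios were Pcp4 (1.19 and 64.3 CPM), Nts, Cma2, Saa3, Cxcl13 (12.9 and 61.6 CPM) and Enho. The lowest after Xist were Rgs13, Ltf, the T-cell receptor gene Trbc2 (58.9 and 6.39 CPM), Plpp1 and Fxyd2 (811 and 136 CPM). Pcp4 and Nts lead Aire-stage cluster 8, and Ltf leads the secretory-like cluster. The class held 157 and 237 cells. Several of these ratios depended on the processing, for reasons that were not tested. Ltf changed sign from -3.56 to 2.24 with doublets kept, and Cma2 from 4.05 to -2.01 with the stricter filter. Cxcl13 went from 2.17 to 4.21 with the stricter filter, and Trbc2 from -3.02 to -1.51 with per-cell CPM.

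Tuft-like cells, though 3.58-fold apart in share, had close levels of the core genes Trpm5 (591 and 575 CPM) and Pou2f3 (135 and 149 CPM). The effector and taste genes split, 9 higher and 8 lower in the library labelled fl/fl, with a median of 0.06 that became -0.01 with TMM factors. The cytokine gene Il25 had 104 (100 to 109) and 202 CPM (192 to 213), and the taste-signalling Gnb3 and Gng13 had 555 and 1106 CPM and 1013 and 1745 CPM. Ptgs1 was lower, at 613 and 339 CPM, and Alox5ap too, at 1208 and 981 CPM. MHC class II genes were higher in 9 of 9 (0.55), with H2-Aa at 238 and 488 CPM, and 10 of 10 measured interferon-stimulated genes were lower (-0.23, Stat2 51.6 and 32.9 CPM). Markers of other classes differed by more, such as Aire-stage (1.57, 7 of 7 higher) and Myeloid and dendritic (1.55, 2 of 3 higher). Immature mTEC markers were lower (-0.45, 7 of 9). Krt19 had 229 and 774 CPM. Highest after the Y-linked genes were the microfold gene Gp2 (15.7 and 164 CPM), Hamp2, Fabp4 and Ptgds, and lowest after Xist and Tsix were Barx1 (73.0 and 11.9 CPM), Ccnj, Pxdc1 and Bhlhe40 (144 and 35.2 CPM). Cluster 5, led by Nrgn and Dclk1, held 1287 of the 1912 cells labelled +/fl, and clusters 6, 5 and 4 held 355, 297 and 186 of the 838 labelled fl/fl.

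Myeloid and dendritic cells lie outside the sorted population and were mostly cluster 9, led by Ccr7 and Cd83, with 347 and 281 cells. The rest were cluster 20, led by C1qa and C1qc, with 11 cells labelled +/fl and 44 labelled fl/fl. The neutrophil granule gene Camp (2.53 and 252 CPM) and also S100a9 (4.15 and 1198 CPM) were higher in the library labelled fl/fl, and Ngp was at least 323-fold higher against 0 UMIs. Interferon-stimulated genes were higher in 12 of 13 (median 0.54), with Irf7 at 21.6 and 57.4 CPM. So were markers of B-lineage cells (2.45, 5 of 5), keratinocytes (2.35, 6 of 7) and enterocyte-hepatocyte cells (2.23, 6 of 7). Apoptosis genes were higher in 11 of 11 (0.38) and stress genes in 14 of 16 (0.21). The dendritic chemokine genes Ccl22 (1039 and 950 CPM) and Ccl5 (6988 and 7025 CPM) were close. Cxcl9 had 225 and 83.8 CPM, and the chemokine median was -0.35. The keratin list was lower (-0.48), with Krt17 at 1071 and 346 CPM. The highest ratios also included Lgals7 and Fabp9 (1.15 and 140 CPM), and the lowest after Xist were Gpx6, Clca3b, Retnla, Calca and Mmp9 (183 and 19.7 CPM). With the stricter filter the Fabp9 ratio went from 6.03 to 2.34 and that of Lgals7 from 6.20 to 3.21. S100a9 leads Aire-stage cluster 8 as well, Fabp9 leads cluster 12, Calca cluster 8 and Gpx6 cluster 3.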

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

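The tests of cell filter, dilution and sex in this part were chosen after the shares had been seen. So were the bounds that picked the gene lists, a median beyond 0.2 on the log2 scale and a place in the outer 2.5% of random lists on either side, in classes with opposite signs.

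Barcodes that failed the cell filter, which only the alternative without a filter uses, also carried Trpm5. It had 326.7 CPM (316.7 to 336.9) in 2205 such barcodes labelled +/fl and 213.7 CPM (203.9 to 223.9) in 2887 labelled fl/fl, where 0 UMIs would allow 0.242 and 0.358 CPM. Without any filter, 35.2% (33.2 to 37.2) and 18.4% (17.03 to 19.9) of these barcodes fell in the Tuft class. Aire in them had 188.7 and 397.8 CPM.

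More Tuft cells and less Aire in the library labelled +/fl was weighed against technical explanations. The cell filter, doublets and depth are argued against as the whole cause, since the log2 ratio of Tuft shares nearest to 0 among 4 alternatives was -1.53 (-1.62 to -1.45). Dilution of the other cells by Tuft cells alone is argued against too. Tuft cells left 68.3% and 91.5% of UMIs to the other cells, which alone would give Aire a log2 ratio of 0.42, and the ratio over all kept cells exceeded that by 0.72 (0.68 to 0.75). The excess counts Aire UMIs, wherever free RNA carried them, and the level per cell enters it, so it does not show that fewer cells were Aire-positive. Shares of cells with an Aire UMI do not settle that either, since T-lineage cells had them in 6.58% and 21.2%. Sex, with Xist at 1317 CPM in the library labelled +/fl, stays open because it cannot be told apart from genotype, and so do genotype itself, a difference between preparations, and an exchange of the labels.

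Chemokines lay on opposite sides between classes, with medians of 0.43 in Aire-stage mTEC and 0.69 in Tuft against -0.35 in Myeloid and dendritic cells. Their difference was not tested, and the first became -0.12 with per-cell CPM and the second -0.25 at 20 CPM or more.

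Interferon-stimulated genes did so as well, with medians of 0.24 in Immature mTEC and 0.54 in Myeloid and dendritic cells against -0.33 in Cycling and -0.23 in Tuft cells. The difference was not tested.

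Keratins had medians of 0.73 in Aire-stage mTEC and -0.48 in Myeloid and dendritic cells, a difference that was not tested.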

How the results depend on the processing

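The sums with a Muscle class were added after the shares had been seen. The rule for calling a value moved (outside its counting interval) and the choice of the 4 list medians given here were also set after values had been seen. No paired analysis was possible because each genotype has 1 library. Values are log2 ratios, labelled fl/fl over labelled +/fl, with the main value in parentheses at first mention. For values that moved or reversed the cause was not tested.

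Tuft cells kept the larger share in the library labelled +/fl under all 11 alternatives for shares, and Ikzf1 was lower in the library labelled fl/fl under all alternatives run over all kept cells (-0.86 to -0.70), in Aire-stage mTEC (-1.51 to -1.01) and in Tuft (-1.64 to -1.39). None of these alternatives compared Ikzf1 within clusters. Aire over all kept cells stayed between 1.03 and 1.24. The Aire-stage share was less firm, since it rests on names. At resolution 0.5 a cluster led, as cluster 3, by Gpx6 and 4922502D21Rik took the muscle name (904 and 114 cells), with libraries clustered apart a cluster labelled +/fl with a like Aire level took the microfold name (670 cells), and at resolution 2 12.5% and 32.3% of cells stayed unnamed.

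By setting, resolution 0.5 moved the share ratios of Aire-stage (1.09) to 3.99, Microfold (2.21) to 2.69 and the other mimetic classes together (1.97) to 2.19. Resolution 2 reversed Aire-stage to -0.25 and unnamed (-3.75) to 1.37 and moved Immature (0.08) to 0.19. Another seed gave Immature -0.24 and unnamed -0.19. Variable genes chosen within each library gave Aire-stage 0.97, Immature -0.05, Keratinocyte (1.63) 2.37 and other mimetic 2.20. Clustering without marker genes gave Aire-stage 1.36, Immature 0.27, Cycling (-0.05) -1.12 and unnamed -2.49. Doublets kept gave Aire-stage 1.29. The stricter filter gave Aire-stage 0.57, Immature -0.08, Tuft (-1.84) -1.99, Microfold 1.79, Myeloid and dendritic (-0.79) -1.04, Endothelial (-1.23) -2.43, unnamed -4.35 and other mimetic 2.53. That sum holds an enterocyte-hepatocyte class of 26 cells labelled +/fl and 703 labelled fl/fl, absent from the main clustering. Smaller such classes entered the sums at resolution 2, with variable genes chosen within each library, with doublets kept and with libraries clustered apart. No filter gave Aire-stage 0.89 and Tuft -1.53. Thinning before clustering gave Aire-stage 1.23, Immature -0.04 and Cycling 0.25. Libraries clustered apart gave Aire-stage 2.61, Tuft -1.18, Neuroendocrine (2.47) 0.03, unnamed -0.70 and other mimetic 0.04, and reversed Microfold to -2.40.

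The sum of other mimetic classes leaves Muscle out. Muscle formed a class under 6 alternatives, each time with the larger share in the library labelled +/fl, as with doublets kept (204 and 60 cells). All 57 cells so named with libraries clustered apart were Tuft in the main clustering, as were 84 of the 904 labelled +/fl at resolution 0.5. The other alternatives were not checked for this. A sum with Muscle was 0.04 at resolution 0.5, 1.04 with doublets kept, 1.24 without a filter, 2.30 with the stricter filter, 1.81 at resolution 2 and -0.05 with libraries clustered apart. The sums near 0 hold cells that were Aire-stage in the main clustering, 819 of the 904 labelled +/fl named Muscle at resolution 0.5 and 597 of the 670 named Microfold with libraries clustered apart. The size of the other sums depended on the clusters, and their direction did not.

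Thinned shares of cells with a marker depended on depth by construction. At 1000 UMIs Dclk1 (-1.65) was -1.78, Krt10 (0.30) 0.04 and Mki67 (0.12) -0.20. At 4000 UMIs Aire (0.95) was 0.84, Cd80 (1.73) 1.36, Dclk1 -1.53, Gp2 (1.75) 1.38 and Krt10 -0.05. Without thinning Aire was 0.41, Cd80 0.88, Chga (1.33) 0.78, Csn2 (1.05) 0.75, Dclk1 -1.32, Fezf2 (0.69) 0.38, Foxj1 (1.22) 0.51, Gp2 0.91, Il25 (-1.01) -1.56 and Trpm5 (-1.77) -1.63, and Krt10 reversed to -0.42. No order is therefore read from Krt10 or Mki67.

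TMM factors moved the median of all genes to -0.13 over all kept cells and to -0.10 in Aire-stage mTEC. Under them Ikzf1 was -0.86 over all kept cells (-0.76), -0.92 in epithelial classes (-0.82) and -1.23 in Aire-stage mTEC (-1.13). The tuft list was -1.53 over all kept cells (-1.44) and -0.01 in Tuft (0.06), the antigens in Aire-stage mTEC (1.87) were 1.42 and their MHC class II genes (0.46) 0.35. Per-cell CPM gave Ikzf1 -1.01 in Aire-stage mTEC and -0.53 in T lineage (-0.12), antigens 1.39 and MHC class II 0.38, and reversed chemokines in Aire-stage mTEC (0.43) to -0.12. A total without mitochondrial, ribosomal protein and haemoglobin genes gave the tuft list -1.50 and MHC class II 0.40. A pseudocount of 5 CPM gave the tuft list -1.24 and antigens 1.01, and one of 0.1 CPM antigens 2.03. A minimum of 20 CPM gave antigens 1.15 and reversed chemokines in Tuft (0.69) to -0.25. Classes from resolution 2 gave Ikzf1 -1.26 in epithelial classes and -1.51 in Aire-stage mTEC, antigens 2.24 and MHC class II 0.38, and reversed Utf1 in Aire-stage mTEC (0.23) to -0.22. The stricter filter gave Ikzf1 in T lineage -0.75 and antigens 2.12, and reversed Cma2 in Cycling (4.05) to -2.01. Doublets kept gave Ikzf1 in T lineage -0.68 and reversed stress genes in Cycling (0.14) to -0.04 and Ltf there (-3.56) to 2.24. No filter gave -0.56, -0.06 and 1.20 for these.

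Of 1358 gene ratios, 4 reversed as given above, 829 stayed inside the counting interval and 513 moved, all with the sign kept, and 8 and 4 had the other sign without counting as reversed. Of 932 such values of list medians, which leave out the 4 list medians chosen above, 4 reversed as given above. The other numbers were 683 and 203, and 18 and 24. The number of cells limits Cycling, with 157 and 237 cells, and the small mimetic classes, where 16 cells labelled +/fl were ciliated-like.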

Other observations

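All tests in this part except that of the cluster mix were chosen after the values they bear on had been seen.

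In the joint clustering the mimetic classes did not move as one. All 5 named mimetic classes other than Tuft took larger shares of the library labelled fl/fl, from 2.87-fold for ciliated-like to 5.55-fold for neuroendocrine-like cells, while Tuft took the larger share of the library labelled +/fl. The smaller Tuft share alone raises the other shares and so enters these folds, and class shares outside Tuft were not compared. With the libraries clustered apart the names shifted, and 597 of 670 cells labelled +/fl named Microfold there were Aire-stage in the joint clustering, so its shares of mimetic classes are not read. Muscle markers, which named 0 clusters of the joint clustering, had a median log2 ratio of -0.63 over all kept cells. In Tuft cluster 4, however, 5 of them met the marker rule, so their ratio is not separate from the Tuft share. Inside Tuft cells Gp2 had 15.7 and 164 CPM and was found in 1.68% (1.14 to 2.38) and 13.1% (10.8 to 15.7) of thinned cells. Its thinned shares in Immature mTECs were 0.566% and 0.560%, but in Myeloid and dendritic cells, given above, the share was larger in the library labelled fl/fl. Microfold markers as a list were higher in Immature mTECs too (0.59, 5 of 7 higher). Gp2 was not alone in Tuft cells. Microfold markers had a median of 1.05 in Tuft cells, Aire-stage markers 1.57 (7 of 7 higher), neuroendocrine markers 0.98 (4 of 4) and enterocyte-hepatocyte markers 0.92 (5 of 6), against -0.04 for tuft markers. Muscle (-0.35, 7 of 9 lower), ciliated (-0.19) and keratinocyte markers (-0.02) did not follow.

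Aire-stage cells fell into clusters that the libraries shared little. Cluster 8, with the highest Aire level, held 0.286% of cells labelled +/fl and 18.6% of those labelled fl/fl, and cluster 3 held 17.2% and 1.24%. The antigen difference may therefore lie partly in which clusters are present. Within cluster 3 the median log2 ratio of the antigens was 0.47 (0.27 to 0.72), the smallest of the 3 clusters with at least 40 cells in both libraries, against 0.49 (0.02 to 1.11) in cluster 7, 1.56 (1.32 to 1.83) in cluster 12 and 1.87 over the class. These medians rest on unlike sets, since 12, 11 and 9 antigens were measured in clusters 3, 7 and 12 against 15 over the class. Of them 9, 7 and 8 were higher in the library labelled fl/fl. The smaller medians within these clusters leave the cluster mix open as an explanation of much of the class-wide value, and clusters held by 1 library could be that library.

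Free RNA is argued against as the whole source of the antigens in Aire-stage cells. In the library labelled fl/fl their CPM was a median of 6.19 times that in Myeloid and dendritic cells, and over 2 times for 14 of 15, all but Fabp9. Scaling by total UMIs is argued against as well, since the smallest median under 3 other scalings was 1.39. What stays open is the cluster mix, sex, genotype and the labels.

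Free RNA from leukocytes is argued against as the only source of Ikzf1 tags in epithelial cells. It would give like levels in all epithelial classes, but Aire-stage cells had 3.84 times (3.22 to 4.62) the Ikzf1 CPM of Immature mTECs in the library labelled fl/fl and 6.92 times (5.87 to 8.21) in the library labelled +/fl. Exchanged genotype labels stay open. Epithelial Ikzf1 was 1.78-fold (1.70 to 1.87) higher in the library labelled +/fl, but leukocytes were not level either. T-lineage Ikzf1 was 1.09-fold higher there, with log2 ratios from -0.75 to -0.10 over the alternatives, and that of Myeloid and dendritic cells 1.38-fold. Neither library came near a loss of the tags, which may lie outside the deleted exons.

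Aire, Csn2 and Trpm5 were also counted outside the classes they mark. Myeloid and dendritic cells had Aire at 134 and 147 CPM and Csn2 at 279 and 257 CPM, above Immature mTECs with 42.5 and 63.4 CPM of Aire and 24.3 and 46.9 CPM of Csn2. Trpm5 had 29.7 and 7.49 CPM in Immature mTECs, 29.1 and 7.21 CPM in Cycling cells and 33.9 and 15.1 CPM in Myeloid and dendritic cells. The tuft list was lower in the library labelled fl/fl in Immature mTECs (-0.99, from -1.28 to -0.20 over the alternatives) and Cycling cells (-1.18, from -1.68 to -0.80). Its median in Myeloid and dendritic cells was -0.02, but ran from -0.74 to -0.01. The ranges of Immature mTECs and Myeloid and dendritic cells overlapped, so no contrast between these classes is read.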
